A study of Homo sapiens with 6 samples.

How the data were processed

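Hi-C, which cross-links chromatin, ligates DNA ends that lie close together and sequences the joined fragments, was carried out on HCT116, an established human colorectal cancer cell line, and on DKO1, a derivative of HCT116 in which the DNA methyltransferase genes DNMT1 and DNMT3B were knocked out. The series holds 6 libraries, 3 per cell line. Per the labels' protocols, the libraries were made with a commercial kit that cuts with a pair of restriction enzymes after formaldehyde cross-linking. The submitters' processing notes name HiC-Pro, HOMER 4.6 and the human build hg19 (GRCh37), without saying which tool made which file. The caller of the domain lists and the filters on reads are not given in the sources used here.

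A compartment track and a list of domains were used for each cell line, and the labels of all 3 replicates of a line name the same files. The replicates were therefore taken as pooled, and each cell line has 1 value per bin and 1 list of domains. Contact maps, which the labels also name, were not used here. The deposited PC1 score is the first principal component of the interaction map, given for bins of 20 kb. Within every chromosome from 1 to 22 and X the deposited scores had a mean of 0 and an SD of 1 in both lines, so they were scaled per chromosome before deposit. The domain lists hold a chromosome, a start and an end on a 40 kb grid, with no score. Of the HCT116 domains 199 overlapped the next domain in the list, and of the DKO1 domains 26 did, and all were kept as deposited. The files used here hold no contact or read counts, so the depth of each map is unknown and no interval that needs it is given.

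Because each cell line has 1 pooled value, no test between the lines was possible and no p-value was computed. Neighbouring bins are not independent and were not treated as replicates. Bins present in both tracks were joined by chromosome and start. A positive deposited PC1 was called compartment A, the open and gene-rich part of the genome, and a negative one compartment B. A bin whose sign differed between the lines was called switched, and consecutive bins switched the same way were joined into runs. A run was called a boundary shift where it touched a bin that already had the new compartment in HCT116, and a new domain otherwise. A run with such bins on both sides, where a whole HCT116 interval took the other sign, also counted as a boundary shift. Chromosomes with r under -0.3 between the tracks were to be left out, and there were 0 of them. Intervals beside genome-wide shares are the 2.5 to 97.5 percentile range of 1000 resamplings of whole chromosomes, and describe variation between chromosomes only. Wilson intervals at 95% beside shares of boundaries found and of whole domains matched, and exact (Clopper-Pearson) intervals beside the shares of domains on X with positive PC1, cover counting error only.

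A boundary was a distinct start or end of a domain. It was called found in the other list within a tolerance of 40 kb. The level given by chance placement, whatever the compartment, was taken from 1000 circular rotations of the DKO1 list within each chromosome. For PC1 at boundaries, each kind of boundary was itself rotated in the same way. Whole domains were matched at a reciprocal overlap of at least 80%. The PC1 of a domain was the mean over its shared bins, and that of a boundary the mean of the bins on its sides. The matching of domains by compartment, the density of domains per compartment, the counts of compartment intervals, the division of chromosome X into blocks and the PC1 of the domains on X were not in the plan and were added after the files had been examined.

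The rule for the regions named and the planned comparisons were set before the data were examined. The rule takes, per direction, the 10 longest runs of at least 200 kb in which 80% of bins had an absolute PC1 above 0.5 SD in at least one line, the 5 runs of at least 200 kb with the largest mean change, and the 5 chromosomes with the highest and the 5 with the lowest switched share. The 5 longest autosomal runs per direction were added after the values were seen, because most of the runs chosen by the rule lay on chromosome X. Alternatives covered the PC1 minimum, the centring, smoothing over 5 bins, the chromosomes included, the domain sizes, the boundary tolerance and the thinning of the longer list. A comparison of gene lists had been planned and was not run, because it needed gene positions on hg19 and the gene table used here is on another build. Regions are therefore named by position and without genes. The run and overlap functions were tested on simulated data, where 200 switched runs planted in the HCT116 track over 140474 bins gave 200 recovered with their position and direction. The planted runs were full sign changes in an otherwise identical track, without noise or boundary shifts. This checks the code only, not the calling of runs in the real tracks. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0.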

Results

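The genome architecture of HCT116 cells was compared with that of their methyltransferase-deficient derivative DKO1, a line known to have lost most of its DNA methylation. The 3 Hi-C libraries of each line were represented by 1 pooled compartment track and 1 pooled list of topologically associating domains, which are stretches of chromatin that contact themselves more than their surroundings. The HCT116 track held 140527 bins of 20 kb and the DKO1 track 140580, of which 140474 were shared. The domain lists held 4289 domains in HCT116 and 1823 in DKO1. Values have no replicate error, since all 3 replicates of a line name the same files and were taken as pooled, and differences are between these maps.

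The A and B compartments of most autosomes were shared between the lines. On the autosomes PC1 correlated across bins with a Pearson r of 0.87, and 19 of 22 autosomes had an r of at least 0.8. Over all shared bins, with X and Y included, the Pearson r was 0.84 and the Spearman rho 0.85. Of these bins, 84.9% kept their compartment. Compartment A made up 53.8% of bins in HCT116 (51.5 to 56.3 over resampled chromosomes) and 48.6% in DKO1 (47.1 to 50.2). Bins that were A in HCT116 and B in DKO1 made up 10.2% of the shared bins (7.54 to 13.3), or 285.26 Mb. The opposite switch covered 4.99% (3.55 to 6.57), or 140.28 Mb, so that A-to-B switches were 2.03 times as frequent (1.52 to 2.76). Among bins of compartment A in HCT116, 18.9% switched, against 10.8% of those in compartment B. On the autosomes alone, A-to-B bins made up 8.92% and B-to-A bins 4.40%. Among bins with an absolute PC1 of at least 0.5 SD in both lines, the shares were 1.51% and 0.81%. Because each chromosome was centred on its mean, the excess of A-to-B switches depends on where 0 lies, and subtracting the median instead gave 6.98% in each direction by construction. With calls from a mixture of 2 distributions per chromosome, an alternative added after seeing the data, the ratio was 1.74 with a range over resampled chromosomes of 0.78 to 3.68.

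The shape of the PC1 values could be compared only within limits. The SD was fixed at 1 by the scaling of the deposited tracks, so that the planned comparison of amplitude gives no information. The mean absolute PC1 of DKO1 over that of HCT116 had a median of 1.00 over 23 chromosomes, with a range from 0.91 to 1.04. Consecutive bins of 1 sign formed 4372 compartment intervals in HCT116 and 5353 in DKO1, with median lengths of 140 kb and 120 kb. After smoothing over 5 bins there were 2722 and 3384 intervals, with median lengths of 420 kb and 300.0 kb. The step between neighbouring bins was larger in DKO1 on 21 of 23 chromosomes, with a median ratio of 1.19. Larger steps can add sign changes, so the higher count in DKO1 was not separated from noise.

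Chromosomes differed widely in how far their compartments were shared. Chromosome 19, which is gene-dense, had the lowest switched share at 5.48% of bins and the highest correlation, with r = 0.96. Low shares were also found on chromosomes 17 (5.57%), 11 (7.02%), 16 (7.61%) and 22 (8.25%). The highest share was that of chromosome X, where 48.0% of bins switched and r was 0.25. Chromosome Y followed with 40.6%, over 64 shared bins only. Then came chromosomes 13 (26.4%), 7 (23.6%) and 5 (21.5%). On chromosome 7 the switches went mainly from A to B, with 19.9% of bins against 3.70% from B to A. Chromosome 5 had 16.1% against 5.34%. On chromosome 13, in contrast, the switches were nearly balanced, at 13.8% and 12.6%. A smaller share of compartment A in DKO1 than in HCT116 was found on 18 of the 23 chromosomes from 1 to 22 and X. The exceptions were chromosomes 3, 4, 6, 21 and 22. On chromosome 21 the share of A was 50.1% in HCT116 and 56.3% in DKO1.

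**Figure D1:**
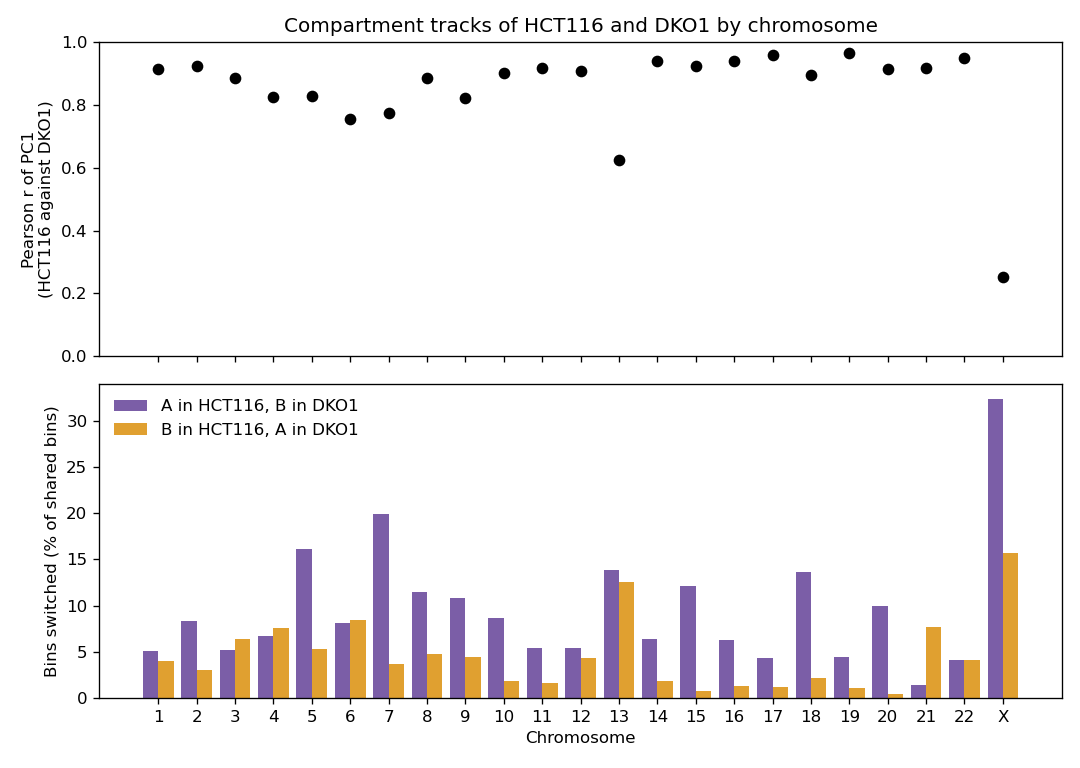
The upper panel plots the Pearson r between the HCT116 and DKO1 PC1 tracks for chromosomes 1 to 22 and X, and the lower panel the percentage of shared bins that switched in each direction. Chromosome X has the lowest r, 0.25, followed by chromosome 13 with 0.62, and chromosomes 7 and 5 have the most A-to-B bins among the autosomes.

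On chromosome X, the sign of PC1 in DKO1 followed blocks many megabases long, whose limits were chosen after the values were seen. From 0 to 70 Mb only 8.30% of its bins were positive in DKO1, against 58.5% in HCT116. From 70 to 120 Mb 89.1% were positive in DKO1 and 53.1% in HCT116. From 120 Mb to the end the shares were 20.3% and 50.6%. Within these blocks r between the lines was 0.13, 0.04 and 0.63, so the last block was as correlated as chromosome 13. Over the whole of X, 54.8% of bins were positive in HCT116 and 38.2% in DKO1. Within 40 kb, 81.5% of the DKO1 domain boundaries on X were found in HCT116, against 92.5% on the autosomes. Of the 77 DKO1 domains on X, 81.8% (71.4 to 89.7) had a positive mean PC1 in the HCT116 track but 35.1% (24.5 to 46.8) in the DKO1 track. These intervals take domains as independent, although in DKO1 those within a block mostly share its sign. On the autosomes, the corresponding shares of 1735 DKO1 domains were 83.7% and 82.8%. The switched bins of chromosome X, which were 16.7% of all A-to-B and 16.5% of all B-to-A bins, are therefore given with this difference beside them.

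**Figure D2:**
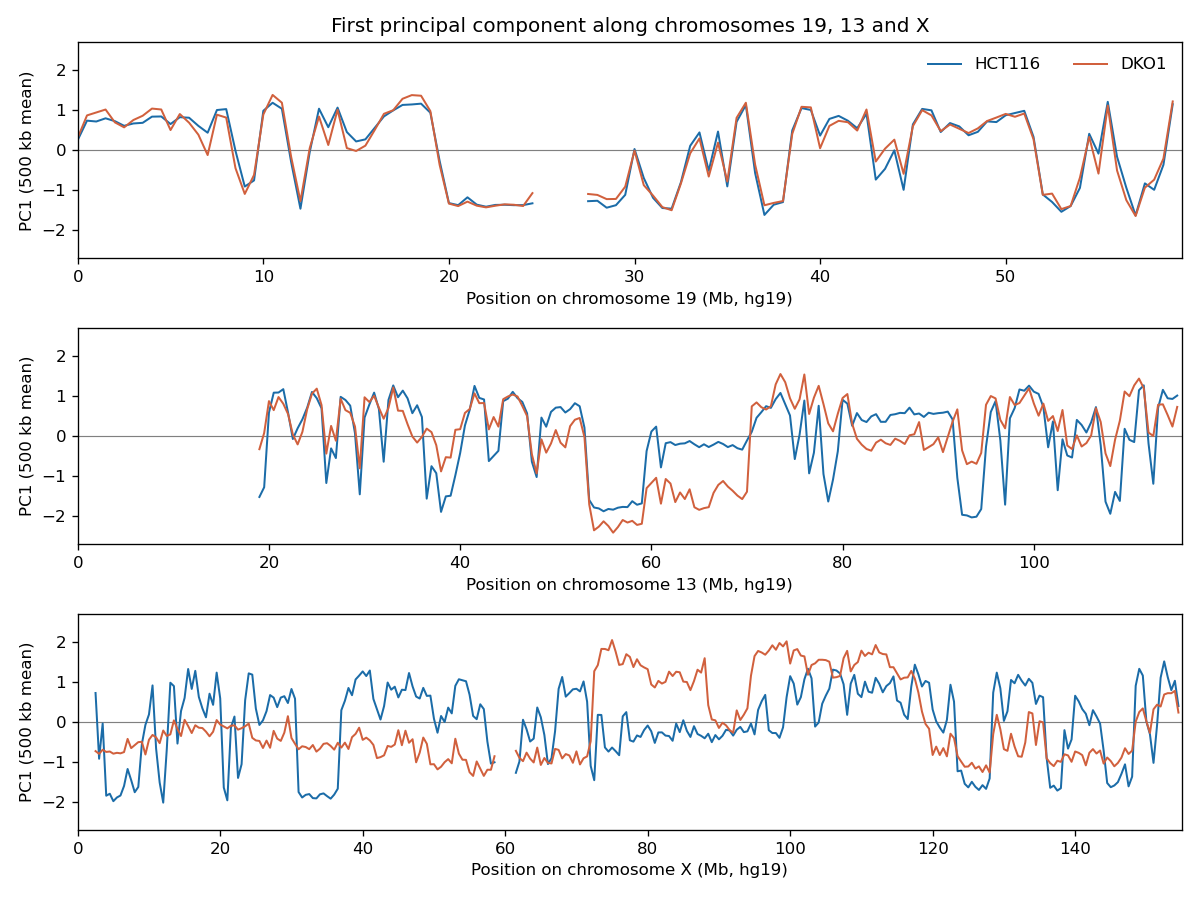
PC1 averaged over 500 kb is plotted against position in Mb (hg19) along chromosomes 19, 13 and X for HCT116 (blue) and DKO1 (orange). The lines nearly coincide on chromosome 19 (r = 0.96) and part on chromosome 13 (r = 0.62), and on X (r = 0.25) the DKO1 line is mostly positive between 70 and 120 Mb and mostly negative elsewhere.

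Most switched bins lay in runs that touched an existing compartment border, and 55.0% of A-to-B and 40.1% of B-to-A bins lay in runs of at least 200 kb. Of the A-to-B bins, 60.4% were in runs called boundary shifts and 39.6% formed new B domains within A. Of the B-to-A bins, 68.8% were in runs called boundary shifts and 31.2% formed new A domains. Runs called boundary shifts can include whole HCT116 intervals that switched, so these shares do not count moved borders alone. Runs of at least 200 kb numbered 369 from A to B, of which 59 lay on X, and 137 from B to A, of which 25 lay on X. A minimum of PC1 in 80% of bins was passed by 123 of the A-to-B and 74 of the B-to-A runs of this length. Among these, the 10 longest A-to-B runs measured 1200 to 2580 kb and the 10 longest B-to-A runs 780 to 2820 kb, and in each direction 8 of the 10 were on X. The longest of all, at positions 73860001 to 76680000 of chromosome X, had a mean PC1 of -0.68 in HCT116 and 1.75 in DKO1, and was touched by 1 HCT116 domain and 0 DKO1 domains. The longest A-to-B run on X, at 39940001 to 42520000, had means of 0.92 and -0.54. It was touched by 4 HCT116 domains and 1 DKO1 domain. The run at 131220001 to 133280000, which formed a new domain, went from 1.04 to -0.72. The largest change in either direction was the B-to-A run at 72460001 to 73120000 of X, with means of -1.29 and 1.21. Of the 5 largest changes, 4 were on X in each direction. The fifth was on chromosome 4 in both, namely an A-to-B run at 30700001 to 31260000 with a difference of -2.12 and a B-to-A run at 22920001 to 23140000 with one of 2.12. On X these values depend on the megabase-scale course of the DKO1 track. After a 10 Mb running mean was subtracted, the run at 42940001 to 45300000 had a difference of 0.00203 in place of -1.36.

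Outside X, and among the runs that passed the PC1 minimum, the longest A-to-B run was at 17940001 to 19200000 of chromosome 1. Its mean PC1 was 0.45 in HCT116 and -0.86 in DKO1, and 4 domains touched it in each line. The next runs in this direction were on chromosome 18 at 36680001 to 37880000 and on chromosome 9 at 113040001 to 114180000, with differences of -1.08 and -1.46. Chromosomes 10, at 10500001 to 11440000, and 13, at 60220001 to 60980000, held the others, with differences of -1.15 and -1.31. Of the 8 longest autosomal A-to-B runs taken without the minimum, the 5 that did not pass it lay on chromosome 7, among them those at 77740001 to 78900000 and 114600001 to 115760000, both of 1160 kb, with differences of -0.86 and -0.74. From B to A, 4 of the 5 longest autosomal runs that passed the minimum were on chromosome 13, while runs of 860 kb on chromosome 3, at 168580001 to 169440000, and of 780 kb on chromosome 21, at 10340001 to 11120000, did not pass it. The longest, at 76460001 to 77340000, had means of -0.81 and 0.70, and was touched by 3 HCT116 domains and 0 DKO1 domains. The run at 78080001 to 78800000 had the largest difference of these, 2.00. The others on chromosome 13 were at 74980001 to 75760000 and 108800001 to 109560000, with differences of 1.22 and 1.72. The fifth, at 169140001 to 169860000 near the end of chromosome 6, formed a new A domain with a difference of 1.79. Median subtraction and smoothing left the direction of all 30 named runs as it was, but the 10 Mb running mean reversed 3 of them, all on X. With these 3 included, it reduced the difference by over 1.5 times in 15 of the 18 named runs on X, as at 39940001 (to -0.36) and 73860001 (from 2.43 to 1.202). Median subtraction did so in 4 runs on X, with -0.96 at 39940001 in place of -1.46, -0.86 at 42940001, -0.94 at 47100001 and -0.76 at 37140001. The running mean also did so in 7 of the 12 named autosomal runs. On chromosome 13 these were at 60220001 (to -0.38), 74980001 (to 0.49) and 76460001 (to 0.82). The others were at 30700001 of chromosome 4 (to -1.13), 113040001 of chromosome 9 (to -0.88), 10500001 of chromosome 10 (to -0.70) and 169140001 of chromosome 6 (to 0.71).

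DKO1 had fewer domains than HCT116 on every chromosome from 1 to 22 and X, at nearly the same size. The ratio of HCT116 to DKO1 was 2.35 over the whole lists. The median domain length was 280 kb in both lines, with quartiles of 240 and 320 kb in both. The length covered by domains was 1336.56 Mb in HCT116 and 620.76 Mb in DKO1. The number in DKO1 as a percentage of that in HCT116 was lowest on chromosome 13, at 24.3%, where 103 domains stood against 25. It was highest on chromosome 19, at 56.7%, with 164 against 93. Of the HCT116 domains, 35.3% (33.9 to 36.8) were matched by a DKO1 domain, and 83.1% (81.3 to 84.8) of the DKO1 domains were matched in HCT116. Among the 2774 HCT116 domains without a match, 87.5% were covered over less than 20% of their length by any DKO1 domain, and 1.05% lay in a DKO1 domain that held several HCT116 domains. The lists also held 18 and 16 entries longer than 2 Mb. Their length was covered by PC1 bins to a median of 15.4% and 15.5%. Leaving them out gave 4271 and 1807 domains, which covered 1245.52 Mb in HCT116 and 522.52 Mb in DKO1. The depth of the maps, which affects how many domains a caller finds, is unknown.

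Most domain boundaries of DKO1 were also listed in the longer HCT116 list. Within 40 kb, 91.9% (90.9 to 92.8) of the 3040 DKO1 boundaries were found in HCT116, while 44.7% (43.5 to 45.9) of the 6366 HCT116 boundaries were found in DKO1. After rotation of the DKO1 list these shares were 26.4% (at most 32.4%) and 12.8% (at most 15.7%) over 1000 rotations. Rotation did not keep boundaries in their compartment. Both lists were denser in A, and the rotated levels do not allow for this shared preference. At the same position exactly, 71.0% and 33.9% were found, against 8.98% and 4.29% after rotation. With the HCT116 list thinned at random to the length of the DKO1 list, 45.9% of DKO1 and 46.1% of HCT116 boundaries were found. Lists of equal length give nearly equal shares by construction. Random thinning also removes HCT116 partners of DKO1 boundaries, so the level of 45.9% does not measure agreement at equal length.

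**Figure D3:**
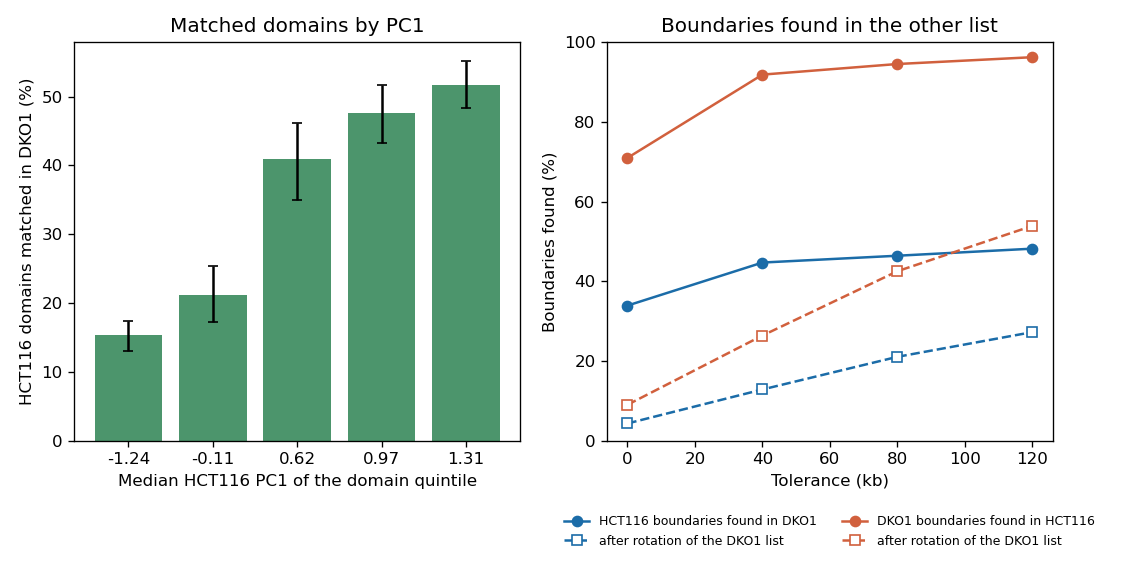
The left panel plots the percentage of HCT116 domains matched in DKO1 for 5 classes of domains ordered by HCT116 PC1, with bars spanning the range over resampled chromosomes. It runs from 15.3% in the lowest class to 51.8% in the highest. The right panel plots the percentage of boundaries found in the other list against the tolerance in kb, with open squares for rotated lists, and 91.9% of DKO1 boundaries were found at 40 kb.

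Domains of compartment A were matched in DKO1 more often than those of compartment B, in a comparison that was not planned. Of the 2907 HCT116 domains in A, 44.1% (40.8 to 47.3 over resampled chromosomes) were matched, against 16.8% (14.8 to 18.7) of the 1370 in B, and A was the better matched on all 23 chromosomes. From the lowest to the highest class of HCT116 PC1 the shares were 15.3%, 21.2%, 40.9%, 47.6% and 51.8%. Domains that were A in both lines were matched in 46.8% of cases. Of the domains that were B in both lines, 16.3% were matched. Domains that switched were matched in 21.9% (13.9 to 28.7) from A to B and in 19.9% (12.6 to 28.5) from B to A, with overlapping ranges. Of the 311 A-to-B domains, 90 lay on X with a median HCT116 PC1 of 0.86, and the other 221 had a median of 0.26. Without X the shares were 20.4% and 21.8%. In HCT116 there were 192.4 domains per 100 Mb of A and 105.5 per 100 Mb of B. In DKO1 the densities were 107.1 and 24.2, each in the compartments of its own track. The matched shares depend on these densities, and no chance level is given here for the matching of whole domains. Compartment A held 68.0% of the domains in HCT116 and 80.7% in DKO1.

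Boundaries differed in the same direction, but they are the ends of the same domains and are not separate support. Boundaries found in both lists had a median HCT116 PC1 of 0.84 (0.79 to 0.90 over resampled chromosomes), and 82.6% of them were in A. Boundaries listed in HCT116 only had a median of 0.17 (0.05 to 0.25), with 55.4% in A, where rotated positions had a median of 0.13 and 53.8% in A. The 221 boundaries listed in DKO1 only and having PC1 values had a median of 0.70 (0.45 to 0.83), and 0.41 with a tolerance of 120 kb. The median difference in PC1, DKO1 minus HCT116, was 0.09 at boundaries in both lists, 0.05 at those of HCT116 only and 0.11 at those of DKO1 only (0.20 with a tolerance of 120 kb), against 0.01 at rotated positions in each case.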

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

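The mixture calls, the removal of X alone, the 10 Mb running mean, the smoothed intervals, the alternatives to the matching by compartment and those to the named runs were chosen after seeing the data, and the others were planned. No paired analysis was possible because all replicates of a line name the same files and were taken as pooled, and no replicate could be left out for the same reason. A stricter caller score could not be tried, since the lists hold none, no chromosome needed its sign turned, and the gene lists were not run. Unit scaling of PC1 at boundaries was not run, because the tracks already have it. In the order HCT116 A share, DKO1 A share, A-to-B share and B-to-A share, in percent, the settings gave the following values. A PC1 minimum of 0.5 SD gave 54.2, 53.5, 1.51 and 0.81. Median subtraction gave 50, 50.0007, 6.98 and 6.98. Autosomes only gave 53.7, 49.2, 8.92 and 4.40, and leaving out X alone gave 53.7, 49.2, 8.93 and 4.40. Leaving out chromosomes 8, 10, 16, 17, 18 and X gave 52.9, 48.9, 8.87 and 4.83, and leaving out those with r under 0.7 gave 53.5, 48.9, 8.74 and 4.09. Mixture calls gave 52.3, 47.3, 11.7 and 6.76. Smoothing gave 4.77 for B to A, and runs of at least 200 kb gave 5.58 and 2.00 for the switched shares. The net change in the share of A was -5.16 percentage points, and -0.70 with the PC1 minimum. It lay between -4.04 and -5.28 under the others, median subtraction apart, which sets it to 0. The correlation stayed between 0.84 and 0.87. Numbers, sizes and covered lengths of domains stayed within 1.5 times. The share of HCT116 boundaries found in DKO1, and of DKO1 boundaries found in HCT116, was 33.9% and 71.0% at tolerance 0, 46.4% and 94.6% at 80 kb, and 48.2% and 96.3% at 120 kb. For whole domains it was 35.3% and 83.1% at 80% overlap and 23.2% and 54.5% at 90%. With the HCT116 list thinned to the length of the DKO1 list it was 46.1% and 45.9%, which lists of equal length must bring close together. The thinning itself lowers the share of DKO1 boundaries found, however well the maps agree. Boundaries of DKO1 only had a median HCT116 PC1 of 0.41 at 120 kb, and a median difference in PC1 of 0.20. At 90% overlap, 29.3% of A and 10.2% of B domains were matched. The direction reversed in 3 named runs on X after the 10 Mb running mean was subtracted, with values of 0.00203 at 42940001, -0.19 at 80520001 and -0.0197 at 82280001. The causes of these changes were not tested beyond what each setting fixes by construction. The depth of both maps is unknown and limits every comparison of domain numbers.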

Other observations

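The removal of X, the joining of domains, the step between neighbouring bins and the absolute correlation over windows on X were tests chosen after related results had been seen, as were the PC1 classes and stretches described first, while the mixture calls, the running mean, the windows with negative r and the domain shares on X were unplanned tests whose outcomes were fixed before they were run.

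The autosomes of DKO1 had fewer bins with a PC1 up to -1.5 and more above 1.5 than those of HCT116. The number of autosomal bins at or below -1.5 was 8009 in DKO1 and 13528 in HCT116, and 8228 bins exceeded 1.5 in DKO1 against 3564 in HCT116. The classes next to these went the other way. From -1.5 to -1.0 there were 17940 bins in DKO1 and 13876 in HCT116, and from 1.0 to 1.5 there were 18568 and 21795. Each track has a mean of 0 and an SD of 1 per chromosome, so the parts of the scale are not independent. The difference within bins, DKO1 minus HCT116, depended on the track that set the classes, and bins chosen at an extreme in either track move towards the middle by chance. Bins with an HCT116 PC1 up to -1.5 had a median difference of 0.26, above 0 on 19 of the 20 autosomes with at least 50 such bins, but bins with a DKO1 PC1 up to -1.5 had one of -0.05, above 0 on 11 of 20. Bins above 1.5 differed by -0.04 with classes from HCT116 and by 0.38 with classes from DKO1, so that the sign changed at both ends. Bins from -0.5 to 0 and from 0 to 0.5 differed by -0.20 and -0.20 with classes from HCT116, and by -0.13 and -0.11 with classes from DKO1.

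Chromosome 13 showed long stretches that took another level in DKO1. From 60 to 70 Mb the mean PC1 was -0.20 in HCT116 (SD over bins 0.23) and -1.44 in DKO1 (SD 0.31). From 82 to 91 Mb it was 0.52 and -0.15, and from 92 to 95 Mb it was -1.81 and -0.35. These stretches were chosen by eye. They held 3, 0 and 0 whole HCT116 domains and 0 DKO1 domains each. Of the boundaries listed in HCT116 only, 16.3% lay within 40 kb of a sign change of HCT116 PC1, against 10.2% (at most 11.8%) after rotation. For boundaries in both lists the share was 11.1%, against 9.66% (at most 11.4%), and for the 246 listed in DKO1 only it was 8.13%, against 9.97% (3.66% to 19.1%).

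For the low correlation between the lines over all of chromosome X, a block of many megabases above a shared finer pattern was argued against. With a 10 Mb running mean subtracted, r was 0.17, against 0.68 on the lowest autosome, chromosome 13. Abrupt block limits leave steps after this subtraction, which can lower r. Within 10 Mb windows on X the median r was 0.29 (-0.52 to 0.81), and 1 of 16 windows reached 0.7. From 120 Mb on, though, the tracks shared a pattern with r = 0.63 as deposited. A sign turned on parts of X met the outcome fixed for it, since r was under -0.3 in 2 of 16 windows of 10 Mb, against 0 of 287 on the autosomes. However, a component computed over a whole chromosome has 1 sign, and the tracks were scaled per chromosome. The negative windows therefore do not by themselves show a turned sign. As the whole cause a turned sign is argued against by the median absolute r of 0.33 over windows on X. A turn alone would leave that value unchanged, and it lay under the 10th percentile of autosomal windows, 0.69. Another candidate explanation is that the first component of the DKO1 map on X does not follow the compartments. The share of DKO1 domains on X with positive PC1 differed by -46.8 percentage points, DKO1 track minus HCT116 track, against -0.92 on the autosomes. Resampling domains gave a range of -58.4 to -36.4. That range is too narrow, because domains within a block of X are not independent in the DKO1 track. HCT116 domains on X also differed, with 72.6% positive in the HCT116 track and 36.3% in the DKO1 track. These shares follow the same DKO1 blocks as the low r, so they are not separate support for this explanation. A true change of compartments or a rearranged X in DKO1 remains open and untested.

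The excess of A-to-B over B-to-A switches did not come from chromosome X, since the ratio was 2.03 without it. Whether it comes from the place of 0 cannot be told apart from a shift of compartments. With mixture calls the ratio was 1.74, but its range over resampled chromosomes, 0.78 to 3.68, included both outcomes. Bins past 0.5 SD in both lines gave 1.86, but this minimum is measured from the same 0 and so cannot decide the question.

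The smaller number of DKO1 domains did not come from joined neighbours, since 1.05% of the unmatched HCT116 domains lay in a DKO1 domain holding several. A lower depth of the DKO1 map may contribute. The median step between neighbouring bins was 1.19 times as large in DKO1 and larger on 21 of 23 chromosomes, which noise could give. The DKO1 track covered 140580 bins against 140527, too small a difference to speak for or against a lower depth. Weaker compartments would also give larger steps relative to the SD. Depth and a loss of domains in DKO1 therefore cannot be told apart, because the files used here hold no contact counts.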
